A study of Mus musculus with 6 samples.

How the data were processed

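RNA was measured in heart ventricles of 1-day-old male mice, with 3 control and 3 Med12cKO libraries. Per the labels' protocols, total RNA was isolated with TRIzol from both ventricles. The deposited values are raw read counts per gene symbol, whole numbers with no normalization, in a table of 24062 symbols whose 6 columns match the sample titles or descriptions. Per the submitters' processing notes, the tools named were TopHat2 2.0.0, featureCounts and edgeR 3.14.0, and the genome build was GRCm38 (mm10). The annotation, strand setting, read length and filters were not given in the sources used here. Reads from overlapping genes on opposite strands, or from near-identical copies, may have been split or lost in counting, which could change the values of single genes. Of the 68 named genes with a position in the annotation, 28 share exon bases with another gene model and 9 share 10% or more of them, and their values are uncertain to that extent.

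Groups and replicate numbers were taken from the sample titles. The labels speak of mice but do not tie each library to a single animal, so p-values measure the spread between these samples. Within a group, counts of every pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of 14.5 to 29.3), so no library was a second sequencing run of another, while 2 libraries from the same animal are not excluded. Depth ran from 8453346 to 10911698 counts, so 3 counts, the upper limit that a count of 0 allows, correspond to between 0.286 and 0.345 CPM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

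The main test was edgeR 4.0.16's quasi-likelihood F test with robust dispersion estimates, in R 4.3.3, on the deposited counts with TMM scaling. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. The standard error is the log2 fold change divided by the square root of the F value. For Med12 an exact two-sided permutation test over the 20 arrangements of the libraries was added. For each of 26 gene lists, fixed for this tissue and target together with markers of other cell types, camera (limma 3.58.1) was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and fry as a rotation test of the list alone, with Benjamini-Hochberg over the lists. Members were also counted with p adjusted over the list alone.

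The groups, tests, gene lists and the alternative settings were fixed before the data were examined. The rule for naming genes took Med12 and the other members of the kinase module, up to 8 genes per direction with the largest change among those with adjusted p under 0.05, an average log2 CPM of at least 1 and separated groups, and up to 6, 3 or 2 called members of each list. Because it gave only 3 genes beyond the kinase module, genes called by DESeq2 or over a list alone were named as well, after their values were seen. The alternatives fixed in advance were DESeq2 1.42.0 (an adjusted p it left undefined stayed so), limma-voom, DESeq2's size factors in edgeR, library totals only, no low-count filter, a filter of at least 1 CPM in all libraries of a group, the replicate number as a block, the letter that opens the sample description as a block or as a subset, each library left out in turn, and a fold above 1.5. Terms for thymus transcripts and for exon length and GC content were added after the data were seen. A library counted as having thymus transcripts when 10 T-cell genes averaged at least 10 CPM, and the length and GC trend was a robust fit with natural splines of 4 degrees of freedom on genes above a log2 CPM of 3, removed as an offset. Length, GC and positions came from GENCODE M21 on GRCm38, which gave a value for 13002 of the 13629 genes tested (95.4%).

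The tests were tested on simulated counts for 13629 genes with the libraries' own means and depths and 50 genes changed at each of 4 fold sizes. For Med12cKO against control, edgeR recovered 12%, 58%, 80% and 88% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold, with 9 false calls, DESeq2 24%, 64%, 78% and 86% with 34 false calls, and limma-voom 12%, 58%, 78% and 90% with 6 false calls. A list moved 1.5-fold in simulation was recovered by camera with an estimated correlation (adjusted p = 7.5e-04) and by fry (6.3e-04). Of 21 unmoved lists 0 were called. Each gene was drawn independently, without thymus or length differences between libraries. The moved list, sarcomere and Z-disc, had an estimated correlation of 0.22 in the real data, and oxidative phosphorylation had 0.93. The simulation therefore does not show how often these list tests would recover such a shift in the real libraries. Recovery of single genes may differ there as well. Results for some single genes are not reported here; they stayed in all tests and counts.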

Results

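Gene expression was measured by RNA-seq in the heart ventricles of 1-day-old male C57/Bl6N mice, a common inbred laboratory strain. Of the 6 libraries, 3 were from control mice without Cre recombinase and 3 from mice that carried Cre for a heart-specific knockout of Med12 (Med12cKO). Med12 is an X-linked subunit of the Mediator kinase module, a part of the complex that links transcription factors to RNA polymerase II. The deposited table held raw read counts for 24062 gene symbols. Totals were 8930340, 10911698 and 10154128 counts in control replicates 1 to 3 and 8453346, 10150557 and 9491374 in Med12cKO replicates 1 to 3. After the filter on low counts, 13629 genes were tested, and 5317 symbols had no count in any library. Values are counts scaled by TMM to a common library size (TMM-scaled CPM) as mean ± SD with n = 3 per group, and positions are those of the mouse GRCm38 build, 1-based.

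The comparison asked how loss of Med12 in the heart changes ventricular expression, and the target itself was examined first. Only the Med12cKO mice carried Cre, so an effect of Cre and an effect of Med12 loss cannot be told apart. This holds for every difference between the groups given below. Med12 (chromosome X, 101274030 to 101297465, plus strand, protein coding) measured 103, 176 and 113 CPM in the control libraries and 61.6, 85.0 and 41.3 CPM in the Med12cKO libraries. Every Med12cKO library lay below every control, and the Med12cKO mean of 62.6 ± 21.8 CPM was 47.9% of the control mean of 131 ± 39.3 CPM. The log2 fold change was −1.06 (SE 0.30). In an exact two-sided permutation test on log2 CPM the p was 0.10, the smallest that 3 against 3 libraries allow. Med12 did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 0.765), and DESeq2 gave an adjusted p of 0.024. The table has a single count per gene, so exons within and outside the deleted part were not separated, and 9.72% of the exon bases of Med12 are also annotated to a second gene model on the same strand. The other members of the kinase module did not pass the test. Cdk8, the kinase of the module, measured 37.0 ± 1.92 CPM in control and 36.8 ± 1.71 CPM in Med12cKO, and Med13 measured 102 ± 2.00 and 102 ± 21.6 CPM. The related subunit Med12l measured 18.04 ± 3.11 and 22.3 ± 4.2 CPM, Med13l 62.3 ± 12.3 and 60.5 ± 21.8 CPM, Cdk19 55.8 ± 10.4 and 52.1 ± 5.80 CPM, and Ccnc 21.7 ± 0.91 and 22.3 ± 2.88 CPM.

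Sbk3 and Sbk2, neighbouring genes for SH3 domain binding kinases, fell in Med12cKO ventricles, and Cnn1, which encodes the smooth muscle actin-binding protein calponin 1, rose. Sbk3 (chromosome 7, 4965260 to 4971168, minus strand) went from 70.9 ± 4.53 CPM in control to 9.34 ± 0.99 CPM in Med12cKO, a log2 fold change of −2.93 (SE 0.14; adjusted p = 4.7e-05, edgeR quasi-likelihood test). Sbk2 (chromosome 7, 4940512 to 4964406, minus strand) went from 47.4 ± 6.61 to 9.31 ± 1.81 CPM, a log2 fold change of −2.34 (SE 0.18; adjusted p = 0.0023, edgeR). Cnn1 (chromosome 9, 22099216 to 22109630, plus strand) went from 28.4 ± 5.25 to 91.9 ± 21.6 CPM, a log2 fold change of 1.70 (SE 0.20; adjusted p = 0.046, edgeR). In each of the 3 genes the groups did not overlap. These were the only genes at an adjusted p under 0.05, 1 higher and 2 lower. With library totals as the only scaling there were 2 higher and 2 lower, and with DESeq2's size factors in edgeR 0 higher and 2 lower (302 higher at an unadjusted p under 0.05). The call of Cnn1 was lost when control replicate 1, 2 or 3 or Med12cKO replicate 3 was left out (edgeR adjusted p of 0.238, 0.276, 0.174 and 0.245), and that of Sbk2 when Med12cKO replicate 3 was left out (adjusted p = 0.051).

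**Figure D1:**
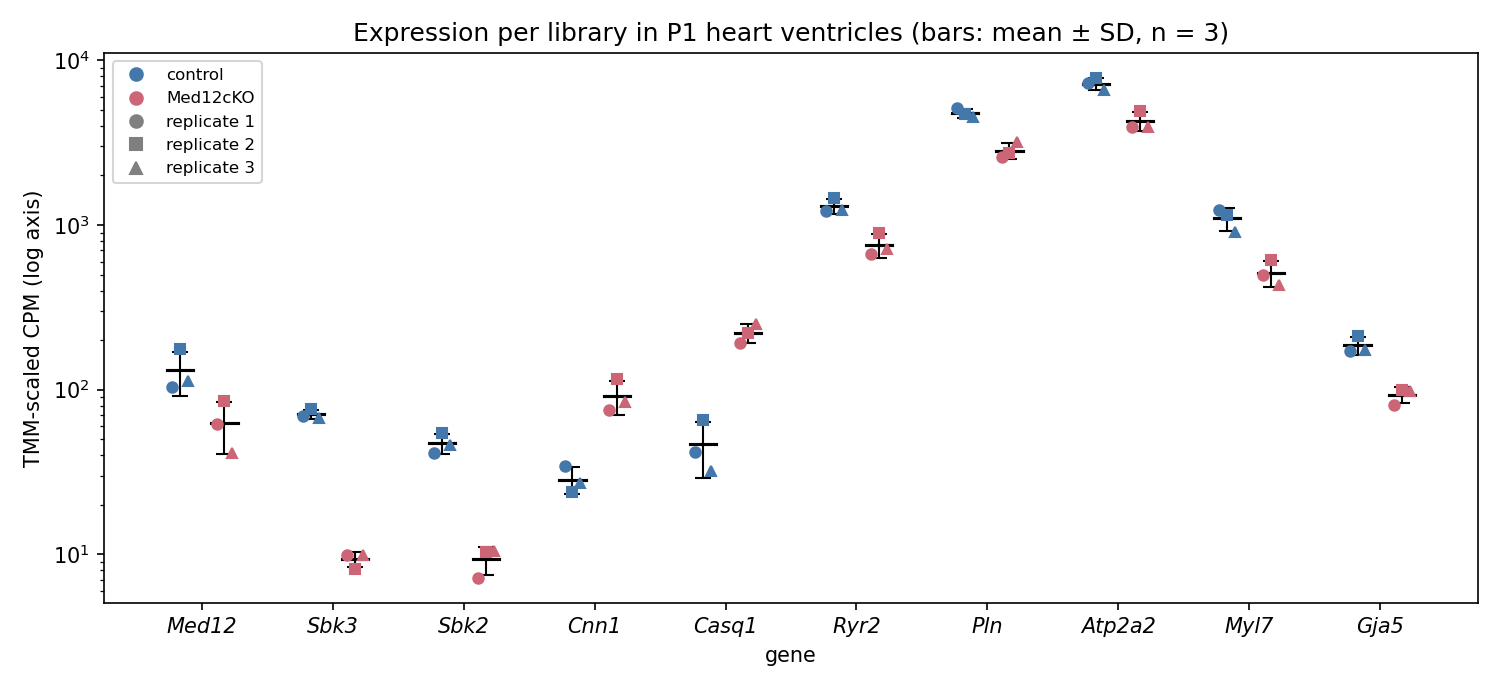
TMM-scaled CPM on a log axis for 10 genes in each of the 6 libraries, with circles, squares and triangles for replicates 1, 2 and 3, blue for control and red for Med12cKO, and bars for the mean ± SD (n = 3). In all 10 genes the 3 Med12cKO libraries lie on one side of the 3 control libraries, and in the edgeR test over all genes Sbk3, Sbk2 and Cnn1 passed an adjusted p of 0.05.

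At an unadjusted p under 0.05 edgeR gave 295 genes higher and 220 lower, 515 in all, where 681 of the 13629 genes would be reached with no effect. The 3 Med12cKO libraries lay all above or all below the 3 controls in 1121 genes, 8.23% of those tested, where chance gives 10%. DESeq2 called 29 genes higher and 32 lower at an adjusted p under 0.05, and all 61 had separated groups and the same sign in edgeR. It called up to 434 genes in other splits of the 6 libraries. Simulated counts had these means and depths, with each gene drawn independently. There edgeR recovered 58% of genes changed 2-fold and 12% of genes changed 1.5-fold, with 9 false calls. DESeq2 recovered 64% and 24%, with 34 false calls. Genes named below from the DESeq2 calls, or from calls adjusted over a list alone, were chosen after their values were seen.

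Genes for calcium handling, the release and uptake of calcium that drive contraction, included Ryr2, Atp2a2 and Pln, which fell, and Casq1, which rose, when p was adjusted over the list alone. The direction of this list is not independent evidence, because the study's published focus was known. None of its 32 members passed edgeR over all genes tested, and DESeq2 called 4. In edgeR 8 of the 32 had an unadjusted p under 0.05, against 515 of all 13629 genes tested. Adjusted over the list alone, 3 members were lower and 1 higher, and 28 did not pass. Ryr2, the calcium release channel of the sarcoplasmic reticulum (chromosome 13, 11553102 to 12106945, minus strand), fell from 1299 ± 138 to 758 ± 124 CPM, a log2 fold change of −0.78 (SE 0.16; edgeR adjusted p = 0.011 over the list alone and 0.300 over all genes). The calcium pump gene Atp2a2 (chromosome 5, 122453513 to 122502225, minus strand) fell from 7214 ± 600 to 4276 ± 572 CPM (log2 fold change −0.75, SE 0.18; edgeR adjusted p = 0.015 over the list alone). Pln, which encodes the inhibitor of that pump (chromosome 10, 53337667 to 53345987, plus strand), fell from 4790 ± 296 to 2829 ± 308 CPM (log2 fold change −0.76, SE 0.16; edgeR adjusted p = 0.011 over the list alone). Of the exon bases of Pln, 59.6% are shared with a gene model on the opposite strand, and strand use in counting was not given in the sources used here. Casq1, the calcium-binding calsequestrin of skeletal muscle (chromosome 1, 172209894 to 172219868, minus strand), rose from 46.5 ± 17.4 to 221 ± 28.3 CPM, a log2 fold change of 2.25 (SE 0.25; edgeR adjusted p = 6.3e-04 over the list alone and 0.068 over all genes). Its cardiac paralog Casq2 had a log2 fold change of 0.42 (SE 0.16) and did not pass. Ryr2, Atp2a2, Pln and Casq1 were the 4 members that DESeq2 called. As a set the list was not called for a shift on balance up or down. Its median log2 fold change was 0.09. Camera gave an upward direction at an adjusted p of 0.232, and adjusted p = 0.727 with an estimated correlation. Fry's mixed test, which takes changes in either direction together, did call the list (adjusted p = 2.9e-06). Leaving out control replicate 2 or Med12cKO replicate 1 brought the camera value to an adjusted p of 0.0021 and 0.012, still upward.

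Of the genes for cardiac conduction and ion channels, 4 of 31 measured members were lower when adjusted over the list alone. They were Gja5 and Gja1, which encode gap junction connexins, and Kcne1 and Kcnip2, which encode potassium channel subunits. Gja5 fell from 186 ± 23.1 to 93.2 ± 10.5 CPM (log2 fold change −0.99, SE 0.14) and Gja1 from 1026 ± 32.7 to 653 ± 16.2 CPM (log2 fold change −0.65, SE 0.12). Camera called the list downward with the preset correlation (adjusted p = 1.7e-07, median log2 fold change −0.14), with adjusted p = 0.315 with an estimated correlation. In the sarcomere and Z-disc list 3 of 34 members were lower over the list alone, namely the atrial myosin light chain gene Myl7, the slow skeletal troponin gene Tnnt1 and Mybphl. Myl7 fell from 1097 ± 175 to 512 ± 89.4 CPM (log2 fold change −1.10, SE 0.18) and Tnnt1 from 64.1 ± 5.07 to 35.6 ± 2.06 CPM (log2 fold change −0.85, SE 0.12). Camera placed this list downward (adjusted p = 4.1e-07), with adjusted p = 0.315 with an estimated correlation. In the cardiac transcription factor list 2 of 28 members were lower over the list alone, among them Hey2 at a log2 fold change of −1.04 (SE 0.15), and camera gave adjusted p = 0.0016, or adjusted p = 0.554 with an estimated correlation. Of 23 cardiac stress genes 1 was higher over the list alone, the ubiquitin hydrolase gene Uchl1 (log2 fold change 0.88, SE 0.15), and camera gave an upward adjusted p of 0.046, or adjusted p = 0.315 with an estimated correlation.

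Metabolic and proliferation lists held no member that passed edgeR, over all genes or over the list alone, or DESeq2. Fatty acid oxidation had 32 of 37 members at a negative log2 fold change (median −0.15; 4 at an unadjusted p under 0.05; camera adjusted p = 1.7e-06, and adjusted p = 0.554 with an estimated correlation). Oxidative phosphorylation had 52 of 73 members at a negative log2 fold change (median −0.05; 0 at an unadjusted p under 0.05; camera adjusted p = 0.019, and adjusted p = 0.759 with an estimated correlation). The cell cycle list had 41 of 42 members at a positive log2 fold change (median 0.19; 1 at an unadjusted p under 0.05; camera adjusted p = 6.3e-04, and adjusted p = 0.677 with an estimated correlation). Its median log2 ratio to the control mean was 0.56 in control replicate 3 and 0.71 in Med12cKO replicate 1, the libraries with thymus transcripts, and between −0.45 and 0.15 in the other 4 libraries. Without Med12cKO replicate 1 the camera direction of the cell cycle list turned downward (adjusted p = 0.717), and without control replicate 2 its call ended (0.974), while it stayed upward and called without control replicate 3 (adjusted p = 6.1e-21), with a term for the libraries with thymus transcripts (6.1e-08) and without those 2 libraries (1.5e-09), all with the preset correlation. With the thymus term and an estimated correlation it was not called (adjusted p = 0.4999, and 0.599 with the length and GC correction as well). Without control replicate 1, Med12cKO replicate 1 or Med12cKO replicate 2 the camera direction of oxidative phosphorylation turned upward and its call ended (adjusted p of 0.285, 0.455 and 0.294), and in the 4 libraries whose description opens with the letter I it was called upward (adjusted p = 8.1e-06). Glycolysis and hypoxia (camera adjusted p = 0.989, with a median of −0.03, a mean of 0.01 and an upward direction), the Mediator kinase module (adjusted p = 0.232) and the Mediator core (adjusted p = 0.783) were not called by camera. In glycolysis and hypoxia 7 of 34 members had an unadjusted p under 0.05, and fry's mixed test gave adjusted p = 0.0084.

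Among the 15 remaining lists, atrial markers stood lower in Med12cKO, with 6 of 19 members lower over the list alone and 15 of 19 at a negative log2 fold change. They included Myl7, Gja5, Dkk3, Mybphl and Tbx5, while Sln, an atrial regulator of the calcium pump, had a log2 fold change of −0.44 (SE 0.16) that did not pass. Tbx5 had a log2 fold change of −0.37 (SE 0.12). It did not pass over the cardiac transcription factor list alone or in DESeq2 (adjusted p = 0.489). The list had a median log2 fold change of −0.37 (camera adjusted p = 8.3e-18, and adjusted p = 0.315 with an estimated correlation). Skeletal muscle markers were higher, with a median log2 fold change of 1.51 over 11 tested members (camera adjusted p = 1.7e-07, and adjusted p = 0.315 with an estimated correlation). Casq1 was the only member that passed over the list alone, and without Med12cKO replicate 1 the call of the list ended (camera adjusted p = 0.079). In that library the median log2 ratio of the list to the control mean was 1.69, against 0.12 and 0.03 in Med12cKO replicates 2 and 3. Smooth muscle and pericyte markers were called upward (camera adjusted p = 0.0039, and adjusted p = 0.554 with an estimated correlation), and Cnn1 alone of 16 members passed. Camera with the preset correlation also called REST-repressed neuronal genes (adjusted p = 4.0e-04), the integrated stress and unfolded protein response (0.023) and fibroblast and matrix markers (0.024) upward, with adjusted p of 0.315, 0.315 and 0.677 with an estimated correlation. The member of the REST list with the largest log2 fold change was a muscle gene, Acta1 (1.54, SE 0.40), which is also in the cardiac stress list and was highest in Med12cKO replicate 1. Camera with the preset correlation called immediate-early genes (adjusted p = 3.8e-05), endothelial markers (0.028), immune markers (0.0047) and epicardial markers (0.014) downward. With an estimated correlation the adjusted p of these 4 lists lay between 0.315 and 0.631. The camera direction turned downward for fibroblast markers without Med12cKO replicate 2 (adjusted p = 0.362), and upward for immune and epicardial markers in the libraries with letter I (0.940 and 0.867). Over the list alone the growth-factor-induced gene Egr1 was lower among immediate-early genes (log2 fold change −1.03, SE 0.18). In the Wnt target list Nkd2 was higher (log2 fold change 1.43, SE 0.25) and Dkk3 lower (−0.65, SE 0.16), and in the p53 and apoptosis list Bcl2l11 was lower (−0.51, SE 0.12). These 2 lists (camera adjusted p of 0.358 each), erythroid markers (0.095), Schwann and neural markers (0.290) and lung and thymus markers (0.642, with 3 of 18 members tested) were not called. In all, camera with the preset correlation called 17 of 26 lists, 7 upward and 10 downward. The lists called in each of the 6 fits that left out a library were 4, namely sarcomere and Z-disc, conduction and ion channels, fatty acid oxidation and atrial markers. Each of the other 13 lost its call in 1 to 4 of these fits. The atrial list shares Myl7, Myl4 and Mybphl with the sarcomere list, and Gja5, Kcnj3 and Kcna5 with the conduction list. The calls of the atrial, sarcomere and conduction lists are therefore not independent of each other. Apart from calcium handling 10 lists were called without Med12cKO replicate 1 and 11 without Med12cKO replicate 2. None was called with an estimated correlation, where the lowest adjusted p was 0.315 and 2 lists had an unadjusted p under 0.05. None was called by fry for a shift on balance in one direction (lowest adjusted p = 0.551, with 1 list at an unadjusted p under 0.05). Fry's mixed test called 11, among them calcium handling, glycolysis and hypoxia and Wnt target genes, which camera did not call.

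DESeq2 also called Acta1, Tpm2, Nppb, Corin, Bmp2 and Oxct1 over all genes, none of which passed edgeR over all genes. Acta1, the skeletal actin, measured 48.9 ± 8.45 CPM in control and 143 ± 78.4 CPM in Med12cKO (DESeq2 log2 fold change 1.55, adjusted p = 3.2e-04), with 232 CPM in Med12cKO replicate 1 and 86.9 and 109 CPM in replicates 2 and 3. The tropomyosin gene Tpm2 measured 147 ± 29.5 and 306 ± 30.0 CPM (DESeq2 log2 fold change 1.06, adjusted p = 1.3e-07). Nppb, which encodes B-type natriuretic peptide, measured 38.7 ± 14.3 and 83.1 ± 26.8 CPM (DESeq2 adjusted p = 0.027), and Corin, a protease that processes natriuretic peptide precursors, 239 ± 54.0 and 147 ± 24.2 CPM (DESeq2 adjusted p = 0.049). Bmp2, a bone morphogenetic protein, measured 10.7 ± 0.57 and 4.47 ± 0.85 CPM (DESeq2 adjusted p = 0.0087). Oxct1, an enzyme of ketone body use, measured 211 ± 21.3 and 317 ± 25.8 CPM (DESeq2 adjusted p = 0.0013). Single gene models on the opposite strand share 12.6% of the exon bases of Oxct1, 18.1% of those of Uchl1 and 15.3% of those of Med12l.

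The libraries also differed in ways that did not follow the groups. Transcripts of developing T cells were present in control replicate 3 and Med12cKO replicate 1, where Rag1 measured 206 and 199 CPM and Cd8a 160 CPM in both, and these genes lay at or below 1.04 CPM in the other 4 libraries. The thymic epithelial gene Foxn1 had 91 and 65 counts in those libraries and 0 in the other 4, where 3 counts would be at most 0.345 CPM. The surfactant gene Sftpc of lung had 314 counts in control replicate 1 and 92 in Med12cKO replicate 2. The liver gene Alb measured 91.2 CPM in Med12cKO replicate 1 and 18.7 CPM in Med12cKO replicate 2. The first principal component (42.7% of the variance) set the libraries with thymus transcripts apart from the other 4. Deviation from the 6-library mean went with exon length across genes, at a Spearman rho of 0.50 in Med12cKO replicate 2 and −0.52 in Med12cKO replicate 3, and 0.34 in control replicate 2 and −0.38 in control replicate 1; these are correlations across 10248 genes, which are not independent replicates. With a term for the libraries with thymus transcripts and a correction for exon length and GC content, both chosen after seeing the data, edgeR called 4 genes higher and 9 lower. Without the 2 libraries with thymus transcripts it called 2 higher and 2 lower.

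**Figure D2:**
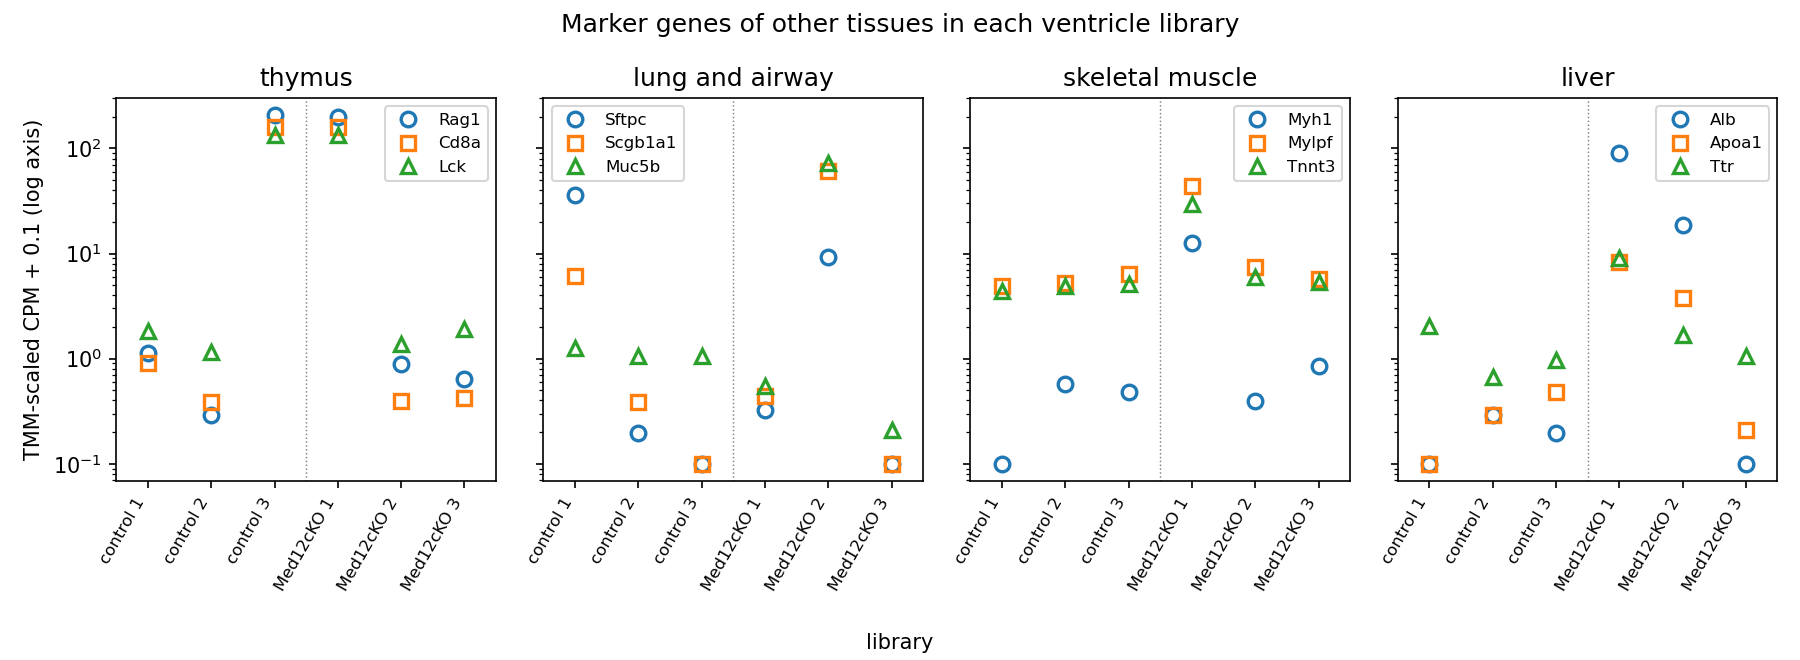
TMM-scaled CPM plus 0.1 on a log axis for 3 marker genes each of thymus, lung and airway, skeletal muscle and liver, for each of the 6 libraries, with a dotted line between control and Med12cKO. Rag1, Cd8a and Lck exceed 100 CPM in control replicate 3 and Med12cKO replicate 1, Scgb1a1 and Muc5b are highest in Med12cKO replicate 2, and Mylpf, Tnnt3 and Alb are highest in Med12cKO replicate 1.

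**Figure D3:**
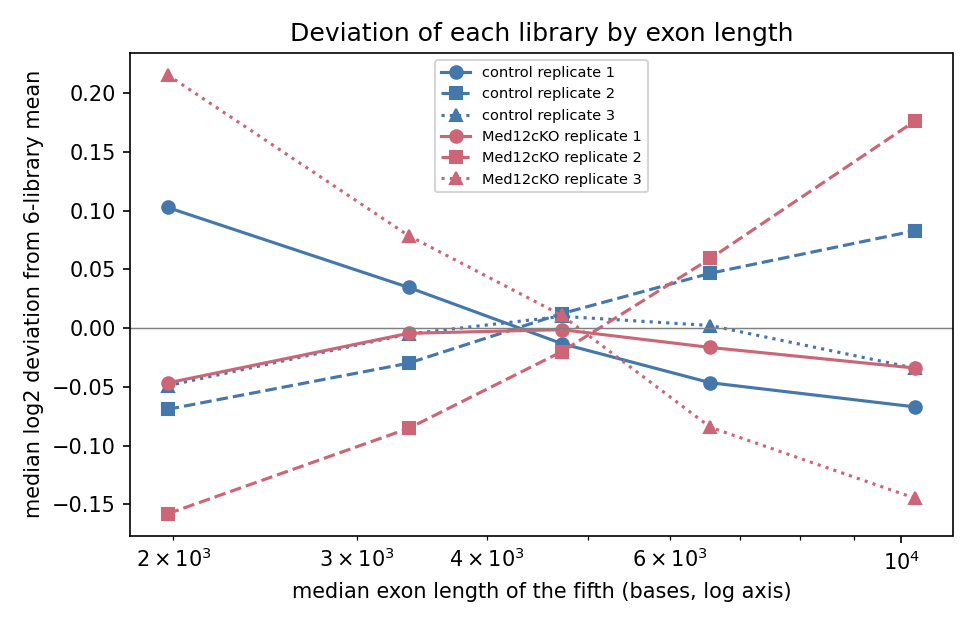
Median log2 deviation of each library from the mean of the 6 libraries, for genes in 5 bins by exon length per gene. Each bin holds 2049 or 2050 genes and is placed at its median exon length in bases on a log axis. Control is in blue and Med12cKO in red. From the bin of shortest to the bin of longest exon length per gene, the median goes from −0.16 to 0.18 in Med12cKO replicate 2. In Med12cKO replicate 3 it goes from 0.22 to −0.14.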

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

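The tests reported here, apart from that on 10 further thymus genes and the split count for lists, were chosen after the result was seen. Of the genes left out of the test for low counts, 14 measured at least 5 CPM in a Med12cKO library and at least 10 times as much as in every control. In Med12cKO replicate 1 these included Alb at 91.2 CPM, Myh1 at 12.4 CPM, Myh2 at 8.57 CPM and Apoa1 at 8.12 CPM, genes of liver and fast skeletal muscle. In Med12cKO replicate 2 they were Muc5b at 72.2 CPM, Scgb1a1 at 61.0 CPM, Cyp2f2 at 36.9 CPM, Sec14l3 at 28.6 CPM, Wfdc2 at 24.5 CPM, Lypd2 at 7.40 CPM, Ccdc108 at 6.41 CPM, Chad at 5.62 CPM and Tspan1 at 5.53 CPM. No gene met this rule by its level in Med12cKO replicate 3. Each rests on a single library, apart from Alb (18.7 CPM) and Apoa1 (3.65 CPM), which were also seen in Med12cKO replicate 2. The reverse search, for genes high in a control library, was not run, so the rule does not show that such transcripts are particular to Med12cKO. The lung gene Sftpc measured 36.1 CPM in control replicate 1 and at most 9.08 CPM in the Med12cKO libraries.

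The first pattern was the low number of calls, 3 genes in edgeR. That control replicate 3 and Med12cKO replicate 1 hold thymus tissue was tested on 10 further thymus genes, of which 6 measured at least 1 CPM in the other 4 libraries. Their median log2 ratio between those 2 libraries and the other 4 was 3.56, with Prss16 at 126 and 0.324 CPM, in line with thymus tissue in both. A term for these 2 libraries gave 4 calls, no more than the 4 of the highest of the 8 other pairs. The length and GC correction alone gave 2. Under that correction Cnn1 kept its log2 fold change of 1.70 but lost its call (edgeR adjusted p = 0.092). Counts this small turn on single genes near the threshold, so they do not decide whether either alone is the whole cause. Both together gave 13 calls, above the 9 of the highest other pair and the 6 of the highest of 20 fits with shuffled lengths and GC. That other pair, control replicate 2 and Med12cKO replicate 3, had no thymus transcripts by the rule used. Deviations from the group means were also most correlated in the thymus pair (0.71), so its term could raise the calls whatever the source of that shared spread. What sets these 2 libraries apart, together with length and GC differences, may account for part of the low number of calls. The counts cannot tie it to thymus RNA, and an effect of Med12 loss limited to few genes stays open.

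The second pattern was the higher skeletal muscle list with Casq1. Without Casq1 the median log2 ratio of the 19 other markers to the control mean was 1.41 in Med12cKO replicate 1 and at most 0.08 in Med12cKO replicates 2 and 3, which is consistent with skeletal muscle RNA in Med12cKO replicate 1 as the source of the list's shift. For Casq1 itself skeletal muscle RNA was excluded as the whole cause: its log2 ratio was 2.10, 2.31 and 2.47 in Med12cKO replicates 1, 2 and 3, and in replicates 2 and 3 it exceeded that of every other skeletal marker with at least 1 CPM in the controls by 1.38 or more. A rise of Casq1 in response to loss of Med12 stays open as a hypothesis. Exon bases shared with a gene model on the opposite strand make up 8.0% of Casq1, and whether they contribute was not tested.

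The third pattern was the lower atrial markers. If the Med12cKO samples held less atrial tissue, Myl7 should follow other atrial genes, but against the mean of Sln, Bmp10, Kcna5, Nr2f1 and Kcnj3 it differed by −0.81 on the log2 scale (SE 0.25), and the 3 Med12cKO libraries, at −0.84, −1.09 and −0.52, lay below the 3 controls, at 0.36, −0.27 and −0.09. Less atrial tissue therefore does not account for all of the Myl7 change. The median of the 13 other list members differed from the same mean by −0.034 (SE 0.34) with overlapping groups, so for them less atrial tissue and a response to loss of Med12 cannot be told apart, since the spread between libraries exceeds the difference.

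The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3 genes in edgeR and the highest other split 0 (with 72 to 1820 genes at an unadjusted p under 0.05), so 1 split reached the real count, and for lists called by camera the real split gave 17 and the highest other 14, again with 1 split at the real count. DESeq2 called 61 genes in the real split and up to 434 in another, that of control replicates 1 and 2 with Med12cKO replicate 3 against the rest, which points to a structure of the samples other than the groups. In 3 further splits DESeq2 called 76, 156 and 203 genes.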

How the results depend on the processing

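Alternatives with a thymus term, a length and GC correction or without the 2 libraries with thymus transcripts were chosen after the data were seen; the others were planned. The 61 genes called by DESeq2 had the same sign in each of the 20 fits that held them. All 61 had separated groups, so leaving out libraries or changing the scaling could hardly turn a sign. Their constant sign is therefore no separate support. Genes without a length were not in the length and GC fits. The number of higher genes, 1, became 0 with DESeq2 size factors in edgeR, with the replicate block, in the libraries with letter I and with the length and GC correction; 2 with library totals only, limma-voom, the thymus term and without the 2 libraries with thymus transcripts; 29 with DESeq2; and 4 with the thymus term and the length and GC correction. Leaving out each library gave 0 to 1, and without control replicate 2 or control replicate 3 the higher gene was Casq1 instead of Cnn1. The number of lower genes, 2, became 32 with DESeq2, 1 in the libraries with letter I and 9 with the thymus term and the length and GC correction, and leaving out each library gave 1 to 2. Where edgeR gave 0 higher genes, 271 to 449 were higher at an unadjusted p under 0.05. Med12 passed with DESeq2 alone (log2 fold change −1.06, adjusted p = 0.024). The calcium handling list had camera adjusted p from 0.0021 to 0.758 when each library was left out, below 0.05 without control replicate 2 and without Med12cKO replicate 1, and up to 0.877 in other settings. Of the 25 other lists, 17 were called; this became 11 in the libraries with letter I, 10 to 15 with each library left out, and 0 with an estimated correlation, with fry, and with either thymus fit when the correlation was estimated. Against the main direction, oxidative phosphorylation turned in the libraries with letter I (camera adjusted p = 8.05e-06) and without control replicate 1 or Med12cKO replicates 1 or 2 (0.285, 0.455 and 0.294, of a leave-one-out range of 3.41e-24 to 0.455), the cell cycle list without Med12cKO replicate 1 (0.717, of a leave-one-out range of 6.06e-21 to 0.974), the fibroblast list without Med12cKO replicate 2 (0.362, the highest of a leave-one-out range from 4.15e-08), and immune (0.940) and epicardial markers (0.867) with letter I. These turns all came in fits on fewer libraries, and their cause was not tested. Nor was that of the other changes between settings, apart from those with the thymus term and the length and GC correction. Replicate numbers did not pair the samples (correlations of same-numbered libraries −0.31, 0.44 and −0.35), and the replicate block gave 0 higher and 2 lower genes and 18 other lists. With the letter as a block there were 1 higher and 2 lower genes, and letter J holds 1 library of each group. Over the single lists apart from calcium handling, 422 values kept direction and side of the threshold, 111 lost and 9 gained a call, and 8 turned. For the named genes apart from Med12, 1224 fits kept direction and side of the threshold, 73 newly passed, 10 no longer passed and none reversed. Outside the kinase module these genes all had separated groups, so a reversal was hardly possible. A gene within 1 SE of 0 was taken to have no direction. No scaling moved the median of all genes by over 0.1. At this depth and n, edgeR recovered 12% of simulated 1.5-fold changes, with each gene drawn independently.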

Other observations

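The test on neighbouring genes was fixed before its result was seen, although Sbk2 and Sbk3 were known as neighbours, and that on sterol genes was chosen after genes of that pathway, among them Sqle, had been seen among the higher genes. Genes of sterol synthesis and uptake, a group that no list covered, leaned higher in Med12cKO, with no single gene passing over all genes. Sqle, which encodes squalene epoxidase, had a log2 fold change of 0.64 (SE 0.19) and did not pass edgeR over all genes (adjusted p = 0.701). The hypothesis of a shared rise was tested on 18 genes of the pathway that had not prompted it. Of these, 16 had a positive log2 fold change, with a median of 0.27, and 5 had all Med12cKO libraries above all controls, where chance gives 10% for both directions together. The 2 largest values were Lss at 0.55 (SE 0.35) and Msmo1 at 0.51 (SE 0.13), and none of the 18 passed edgeR over all genes or DESeq2, with 4 at an unadjusted p under 0.05. Camera with an estimated correlation gave p = 0.0065 and fry gave p = 0.0036 for this single list. With the thymus term the estimated-correlation p was 0.014, and with the length and GC correction as well 0.028. In the 9 other splits of the libraries the lowest p was 0.205. A modest shared rise of sterol genes may accompany loss of Med12, and 3 against 3 libraries do not allow a split share under 0.05.

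The 59 DESeq2 calls with a position were tested for lying close together. There were 5 pairs within 100 kb, where 10000 draws of genes matched on mean expression had a median of 0, and 4 draws reached as many (permutation p = 5.0e-04). The pairs were Sbk2 and Sbk3, 854 bases apart, Sbk2 and Zfp579, Sbk3 and Zfp579, all on chromosome 7 and all lower, Casq1 and Pea15a on chromosome 1, 3090 bases apart and both higher, and Mybpc2 and Myh14 on chromosome 7, both higher. Sbk2 and Sbk3 are related genes and were known before, and 3 of the 5 pairs rest on their stretch of chromosome 7. Of the 10000 draws, 1028 had at least 2 pairs, the number outside that stretch, so the values do not show that called genes lie close together beyond it.

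Further liver and airway genes written down as checks gave these values. In Med12cKO replicate 1 Ttr measured 9.02 CPM and Apoa2 8.68 CPM, against at most 1.96 and 1.40 CPM in the other libraries. In Med12cKO replicate 2 Scgb3a2 measured 309 CPM, Scgb3a1 94.5 CPM and Cbr2 43.2 CPM, against at most 5.29, 2.76 and 7.78 CPM in the others. The fetal liver gene Afp measured 7.50 CPM in Med12cKO replicate 2 and at most 0.861 CPM elsewhere, and Foxj1 and Tekt1 were highest there as well (6.51 and 2.57 CPM). Other checks did not single out 1 library: Ahsg of liver was level over the 6 libraries (16.9 to 24.8 CPM), Fgb measured 3.04 and 2.47 CPM, Fga 1.92 and 1.87 CPM and Apoh 2.48 and 0.888 CPM in Med12cKO replicates 1 and 2, and Krt5 12.5 CPM in control replicate 3 and 7.33 CPM in Med12cKO replicate 1. Bpifa1 stayed under 1 CPM in every library.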
